A study of Mus musculus with 2 samples.

How the data were processed

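Total RNA from mouse embryonic stem (ES) cells was hybridised to Affymetrix Mouse Genome 430 2.0 arrays, 1 array from a control culture and 1 from a culture labelled as a Dnmt1 knockout (KO). Per the labels' protocols, RNA was purified by phenol-based extraction and spin columns, and labelled with biotin after 1 cycle of cRNA amplification. Groups were taken from the sample titles. The source name of both samples described a control, so the title alone marks the KO array.

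Per the submitters' processing notes, the deposited signal intensities were made with MAS5, the Affymetrix algorithm that summarises the perfect-match and mismatch probes of a probe set into 1 linear signal. The target intensity, any scaling between arrays, and detection calls are not given in the sources used here. The values were linear, with a lowest value of 0 on both arrays. The 2 arrays had not been brought to a common level, since the mean after trimming 2% of probe sets at each end was 184.7 on the control array and 247.6 on the KO array. Without detection calls, a probe set at a low signal could not be called present or absent, and the number of arrays limits the precision of every value.

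The 45101 probe sets included 64 Affymetrix control probe sets, which were left out of the gene values. Probe sets were named from the platform annotation, in which 34958 had 1 gene symbol, 932 had several and 9211 were not listed with a gene. No gene was named from a probe set with several symbols. Symbols were updated through gene identifiers to the RefSeq table of assembly GRCm38.p6, which held 34741 of the 34945 single-gene probe sets outside the controls. That table also gave each gene's chromosome and gene order. It is not stated which assembly the array annotation used, so no base positions are given.

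Values were handled on the log2 scale as deposited. Signals below an array's own median over all non-control probe sets were raised to that median, the floor, which was 60.9 on the control array and 74.2 on the KO array. Each gene was represented by its brightest probe set, by the mean of the floored log2 signals. A gene at the floor on 1 array has only a lower bound for its ratio, written as at least N-fold, and a gene at the floor on both arrays has no ratio. Because the median log2 ratio of the genes above the floor on both arrays was 0.43 rather than 0, ratios are given relative to that shift unless they are called as deposited. A constant shift changes no rank among genes.

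With 1 array per group, no test between groups exists and no p-value is given. Genes were counted when their ratio was at least 2-fold. As a technical scale, the SD between probe sets of one gene, pooled over 4704 genes with at least 2 probe sets above the floor on both arrays, was 0.24 on the log2 scale. It covers neither culture nor array differences. For each of 25 gene lists, the median log2 ratio over the members above the floor on at least 1 array was ranked among the medians of 10000 random gene lists of the same size, matched on mean expression in 20 bins. A list with fewer than 5 such genes was given no percentile. The percentile describes these 2 arrays and is not a test of the genotype. The same was done for the genes of each chromosome, over genes above the floor on both arrays.

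The groups, gene lists, floor, fold threshold and the rule for named genes were fixed before the data were examined, as were the alternative settings unless stated otherwise. Centring was among those alternatives, and giving the ratios relative to the shift throughout was decided after the shift was seen. Named were Dnmt1, the 10 genes with the largest ratio in each direction among genes above the floor on both arrays whose probe sets there had 1 sign, the 5 largest bounds in each direction with the bright array at least 4-fold above the floor, and up to 4 members per list with the largest ratios. List members were ranked both on the ratio as deposited, as fixed, and on the ratio relative to the shift, a step added after the shift was seen. Genes named outside that rule are marked as chosen after their values were seen. The lists covered DNA methylation machinery, germline and meiosis genes, X-linked germline gene families, paternally and maternally expressed imprinted genes, pluripotency, 2-cell-like, trophoblast, primitive and visceral endoderm, mesoderm, epiblast and neuroectoderm, Hox, Polycomb, heterochromatin, p53 target, interferon and antigen presentation, fibroblast, hypoxia and glycolysis, heat shock and unfolded protein, amino acid response, immediate early, cholesterol synthesis, proliferation, ribosomal protein and sex-chromosome genes.

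The procedure was tested on simulated data, in which a second array was made from the control array over 18193 genes. All 100 genes made 4-fold higher and 76 of 100 made 4-fold lower were called, as was 1 unchanged gene. The simulated noise had the same size at every signal level and held no difference between cultures. These counts therefore give no rate of false calls for the real arrays. Of 1000 lists drawn at random from all simulated genes above a floor, changed genes included, 4.8% lay outside the middle 95% of random lists. These lists and the random lists came from the same genes, so such a share was built in and checks only the ranking step. Alternatives covered the scaling between arrays (quantile normalization, centring, and a lowess correction with a span of 0.3), the floor (25th percentile, 75th percentile, none), the rule for genes with several probe sets, the fold threshold and the matching of random lists. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 were used.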

Results

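Expression was compared between mouse ES cells labelled as a knockout of Dnmt1, the enzyme that maintains DNA methylation after replication, and their control culture. The stated purpose was to provide a KO control for other experiments on ES cell differentiation. There was 1 array per group, so each value below is a single measurement and no difference could be set against a spread between replicates. Of 18193 genes with a single-gene probe set, 10995 were above the floor on both arrays, 1231 on 1 array and 5967 on neither. The log2 signals of probe sets above the floor on both arrays correlated across probe sets at r = 0.973, which is not a measure over independent replicates. Most genes were brighter on the KO array. The median gene was 1.34-fold higher on it as deposited, a shift of 0.43 on the log2 scale, and ratios below are relative to this shift. The Affymetrix spike-in controls did not share the shift, since their median log2 ratio over 9 probe sets was -0.12 (range -0.38 to 0.05). The ratio of 3' to 5' signal was 1.29 and 1.25 for Actb and 0.73 and 0.80 for Gapdh on the control and KO arrays, and the 3 probe sets for 18S ribosomal RNA had a median log2 ratio of -0.69 as deposited.

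Dnmt1 itself was the gene with the lowest ratio on the KO array. Its brightest probe set gave a signal of 1949.1 on the control array and 262.1 on the KO array, 9.99-fold lower relative to the shift and 7.44-fold lower as deposited. The other Dnmt1 probe sets went from 874.7 and 348.3 on the control array to below the floor on the KO array, so they were at least 15.8-fold and at least 6.3-fold lower. Which of these probe sets lies in the deleted part of the gene is not given in the labels. Among 17 measured genes of the DNA methylation machinery, Dnmt1 was the only one at least 2-fold different relative to the shift, while Dnmt3l and Dnmt3a were also 2.14-fold higher as deposited. The de novo methylation genes Dnmt3l (2877.6 to 6167.0) and Dnmt3a (554.7 to 1187.2) had log2 ratios of 0.67 each, but the 5 probe sets of Dnmt3a averaged 0.42 ± 0.21 (SD between probe sets). Tet2, a methylcytosine dioxygenase, and Mbd2, a methyl-CpG binding protein, had log2 ratios of -0.26 and 0.18, and the 2 probe sets of Mbd2 differed in sign (0.04 ± 0.20, SD). The list as a whole had a median of -0.09 relative to the shift and 0.33 as deposited, at the 17.1 percentile of matched random lists. With the mean over probe sets in place of the brightest, the list moved to the 0.78 percentile.

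Relative to the shift, 133 genes were at least 2-fold higher and 65 at least 2-fold lower on the KO array, out of 12226 above the floor on at least 1 array. As deposited, the counts were 602 and 12. The higher genes were 67.2% of the sum of both relative to the shift and 98.0% as deposited. Khdc3, a maternal factor of the oocyte and early embryo, went from 67.7 to 754.2, 8.30-fold higher. Rhox5, a homeobox gene of reproductive tissues on the X chromosome, went from 314.1 to 3245.8 (7.70-fold). Cox7b2 and Rpl39l, testis-enriched paralogs of a cytochrome c oxidase subunit and a ribosomal protein, were 7.11-fold and 5.25-fold higher. The Cox7b2 signal went from 61.3 to 585.1. Its control signal was only just above the floor of 60.9, so its ratio is close to a bound. Also among the 10 highest were Gm364 (6.94-fold), Gm6958 (6.26-fold), Pnma5 of the paraneoplastic antigen family (5.76-fold), the deubiquitinase family gene Usp17la (4.42-fold), Gm9222 (4.30-fold) and the pluripotency factor Klf4 (3.77-fold). The probe sets of Usp17la, Gm6958, Gm9222 and the Rhox genes belong to multigene families, so related copies could contribute to their signal.

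The largest bounds were for genes at the floor on the control array alone. Rhox6 was at least 7.37-fold higher on the KO array, Efhc2 at least 6.74-fold, the germ-cell ADP/ATP carrier Slc25a31 at least 6.01-fold, the meiotic recombination gene Rec114 at least 5.32-fold and the RNA export family gene Nxf3 at least 5.20-fold. No gene met the same criterion in the other direction. Below Dnmt1, the lowest gene was Grb10, an imprinted adaptor of insulin receptor signalling, which went from 1176.5 to 331.8 (4.76-fold lower, with a log2 mean of -1.97 ± 0.40, SD over 2 probe sets). Ccdc138 was 4.45-fold lower, the ribosomal protein gene Rps27 3.84-fold, the lysophosphatidic acid receptor Lpar4 3.17-fold (log2 mean -1.41 ± 0.36, SD over 2 probe sets), Misp3 2.88-fold and the Wnt ligand Wnt7a 2.82-fold. Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, and Wls, which is needed for Wnt secretion, were both 2.77-fold lower, and the actin-binding gene Tagln was 2.75-fold lower. Misp3 lies on chromosome 8, whose genes were lower as a whole. Without chromosome 8, a setting added after the data were seen, 132 genes were higher and 52 lower.

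**Figure D1:**
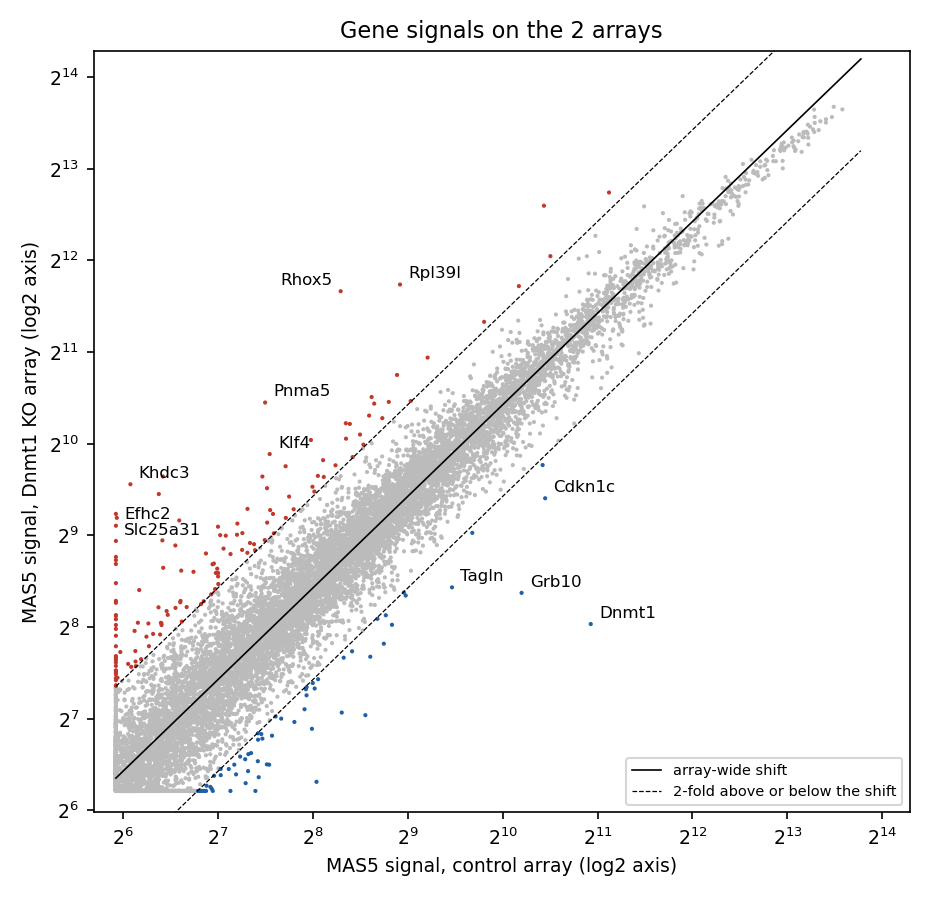
MAS5 signals of the genes above the floor on at least 1 array, control array on the x axis and Dnmt1 KO array on the y axis, both on log2 axes, with signals below an array's floor drawn at the floor. Red points are the 133 genes at least 2-fold above the array-wide shift (solid line) and blue points the 65 at least 2-fold below it, with Dnmt1 farthest below.

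Germline genes were higher on the KO array as a group. Of 27 measured germline and meiosis genes, 9 were at least 2-fold higher and none was 2-fold lower relative to the shift (11 and 0 as deposited). Their median log2 ratio was 0.46, at the 100 percentile of the 10000 random lists, whose middle 95% ran from -0.17 to 0.14. Slc25a31 led the list. Dazl, an RNA-binding protein of germ cells, had a log2 ratio of at least 1.91 (59.5 to 307.8), the meiotic chromosome axis gene Hormad1 at least 1.63 (27.5 to 252.6), and the germ-cell transcription factor Sohlh2 1.55 (130.4 to 513.3). Members that did not reach 2-fold included genes chosen here after their values were seen: Ddx4, a germ-cell RNA helicase, at -0.05 and the meiotic genes Sycp3 at -0.64 and Dmc1 at -0.13. Of 40 listed members of X-linked germline gene families, 18 had a single-gene probe set, and 4 of these were below the floor on both arrays. Of the 14 measured, 6 were at least 2-fold higher and none lower (7 and 0 as deposited), with a median of 0.71. Rhox5 and Rhox6 were followed by Rhox9 (98.1 to 392.6, log2 ratio 1.58) and Fmr1nb (393.8 to 1458.7, 1.46). Rhox13, named after its value was seen, was also among the 6 (1.22).

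**Figure D2:**
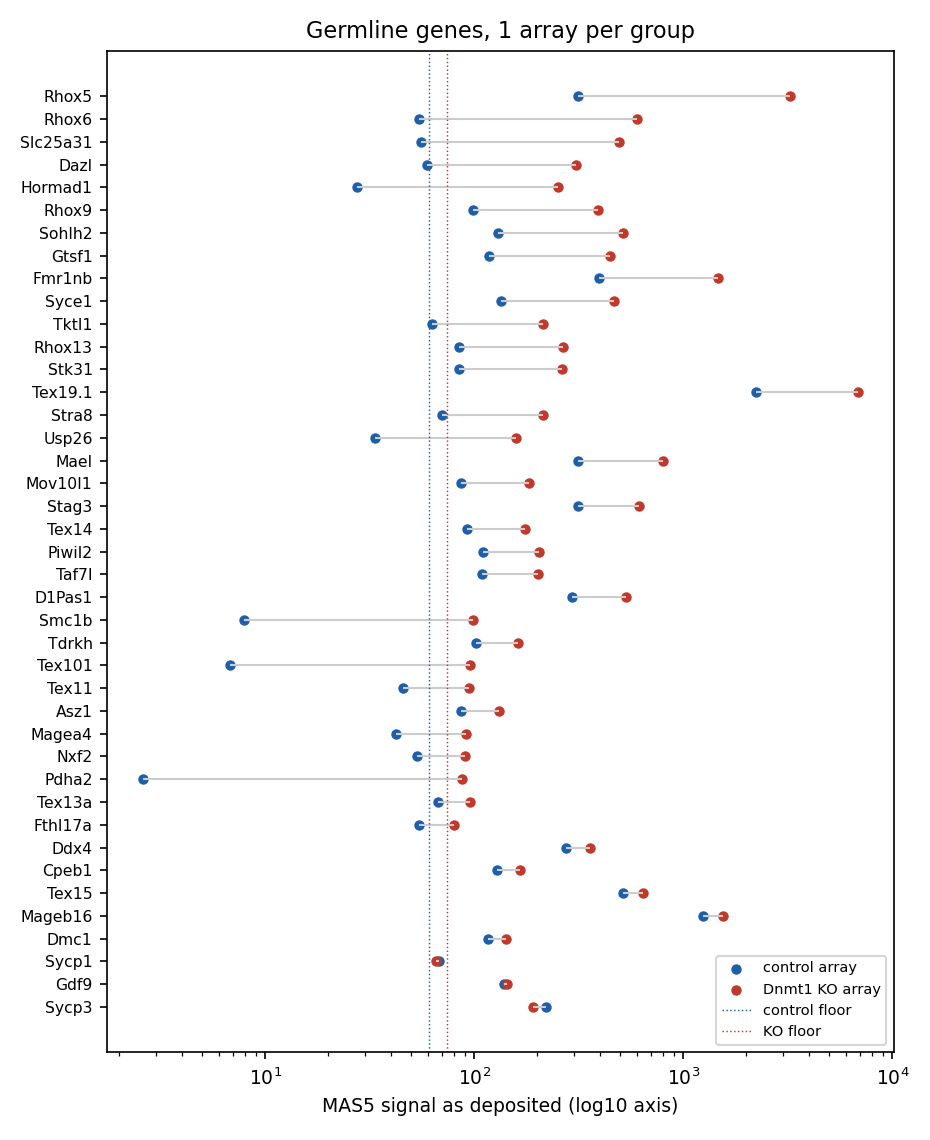
Deposited MAS5 signals, on a log10 axis, of the measured members of the germline and meiosis list and of the X-linked germline list, 1 control value (blue) and 1 KO value (red) per gene, ordered by ratio, with the floor of each array as a dotted line. Rhox5 at the top goes from 314.1 to 3245.8, and Sycp3 at the bottom from 220.6 to 190.8.

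Imprinted genes were listed by the parental origin of the expressed copy. Of 20 measured paternally expressed genes, 16 lay above the shift, 3 were at least 2-fold higher and none was 2-fold lower (8 and 0 as deposited), and the median of 0.40 lay at the 100 percentile. Dlk1, a Notch-related membrane protein, went from 159.1 to 626.1 (log2 ratio 1.55), Sgce from 76.1 to 238.2 (1.22), Peg3, a zinc finger gene, from 1153.6 to 3373.7 (1.12, with a mean of 1.41 ± 0.50, SD over 3 probe sets), and Magel2 from 153.8 to 351.3 (0.77). Of 19 measured maternally expressed genes, 2 were at least 2-fold lower and none was 2-fold higher relative to the shift, whereas 2 were 2-fold lower and 2 were 2-fold higher as deposited. Those lower were Grb10 and Cdkn1c. Ppp1r9a and Calcr had log2 ratios of -0.99 and at most -0.98, while Ascl2, a trophoblast transcription factor, and the noncoding RNA Rian had 0.71 (0.82 ± 0.42, SD over 3 probe sets) and 0.65 (0.33 ± 0.37, SD over 4). The median of the maternally expressed list was -0.12 relative to the shift and 0.30 as deposited, at the 5.86 percentile, and it moved to the 1.7 percentile with quantile normalization. The difference between the parental lists was not tested.

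Among 30 measured pluripotency genes, 5 were at least 2-fold higher and none lower (7 and 0 as deposited), but the list median of 0.02 was at the 75.6 percentile. Klf4 went from 187.1 to 947.8 (1.61 ± 0.43, SD over 2 probe sets), Nr0b1, an orphan nuclear receptor, from 147.8 to 560.2 (2.82-fold), Nanog from 592.5 to 1965.5 (1.31) and Esrrb from 361.8 to 1098.1 (0.84 ± 0.40, SD over 3 probe sets). The core factors Pou5f1 and Sox2, chosen after their values were seen, had log2 ratios of -0.13 and -0.07. Of 7 measured 2-cell-like genes, which mark a rare ES cell state, Usp17la and the autophagy receptor Calcoco2 (183.5 to 732.1) were at least 2-fold higher, or 5 of the 7 as deposited, and none was lower. Arg2 had a log2 ratio of at least 0.86 and Ddit4l 0.66 (0.60 ± 0.48, SD over 3 probe sets), and the list was at the 99.99 percentile. No Zscan4 gene, the best known markers of this state, had a single-gene probe set, and Tcstv1, Tcstv3, Pramel7 and Tdpoz1 were below the floor on both arrays. Of 18 measured trophoblast markers, 4 were at least 2-fold higher and none lower (5 and 0 as deposited), with a median of 0.31 at the 100 percentile. These were the hormone gene Sct (86.0 to 401.0, 1.80), the transcription factor Tfap2c (446.3 to 1405.5, 1.23), the keratin Krt7 (at least 1.17) and Plac1 (1.03). The trophoblast regulators Cdx2 and Eomes, chosen after their values were seen, had log2 ratios of -0.36 or below and of -0.27. Of 23 trophoblast markers on the array, 5 were below the floor on both arrays, namely Elf5, Gata3, Tpbpa, Ctsq and Psg17. Peg10 and Ascl2 were shared between this list and the imprinted lists.

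Lists of differentiated cell markers lay on both sides of the shift. Of 25 epiblast and neuroectoderm markers on the array, 15 were below the floor on both arrays. Of the 10 measured, none was 2-fold different, but 8 lay below the shift, and the median was -0.41 at the 0.01 percentile. As deposited that median was 0.01, so its direction depended on the scaling, and the list was at the 7.26 percentile without a floor. The transcription factor Sox11 went from 737.6 to 589.0 (-0.70 ± 0.09, SD over 5 probe sets), Nes, an intermediate filament of neural progenitors, had -0.50, Pax6 -0.52 and Six3 -0.85 or below, while Pou3f1 and Sox3 had 0.30 and 0.29 and Zic2 -0.02 or above. Of 25 fibroblast markers on the array, which feeder cells would carry, 9 were below the floor on both arrays. Of the 16 measured, 12 lay below the shift and Tagln was the only one 2-fold lower. Their median was -0.29 relative to the shift and 0.14 as deposited, at the 0.13 percentile, or the 12.9 percentile over the 8 genes left with a floor at the 75th percentile. Col1a1, an abundant collagen of fibroblasts, was 94.3 on the control array and 80.2 on the KO array, near the floor of both, Mmp2, on chromosome 8, had -0.57, and Vim, Col5a1 and Thy1 had 0.54, 0.37 and 0.27. Endoderm markers had a median of 0.12 at the 89.1 percentile. The members with the largest ratios in size were Hnf4a at -1.35 or below, with another probe set of the gene at -0.01, Gata4 at -0.54 or below, Srgn at 0.49 or above and Sparc at 0.46, whose 3 probe sets averaged 0.02 ± 0.62 (SD). Mesoderm and primitive streak markers (8 measured, -0.16, 21.9 percentile) and Hox genes (5 measured of 33 on the array, -0.13, 29.4 percentile) lay within the range of random lists.

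Target genes of p53 were slightly higher as a group. None of the 20 measured genes was 2-fold different relative to the shift (2 higher and 0 lower as deposited), 17 lay above it, and the median was 0.23 at the 99.92 percentile. Pmaip1, a pro-apoptotic gene, had a log2 ratio of 0.83, the cell cycle inhibitor Cdkn1a 0.67, Trp53inp1 0.51 (0.29 ± 0.31, SD over 2 probe sets) and Phlda3 0.50. Ribosomal protein genes were lower relative to the shift, with a median of -0.15 at the 0.59 percentile, and higher as deposited at 0.27. Rps20 had a log2 ratio of -0.33 and Rpl14 0.23. They entered the range of random lists under quantile normalization (66.8 percentile) and lowess (30.6 percentile). The remaining 10 lists lay inside the middle 95% of random lists in the main setting. Interferon genes moved above it with a floor at the 75th percentile (97.95 percentile), and immediate early genes without chromosome 8 (99.77 percentile). As deposited, 3 Polycomb, 3 interferon, 2 heat shock, 2 immediate early, 1 heterochromatin, 1 hypoxia, 1 amino acid response and 1 proliferation gene were at least 2-fold higher and none was lower. The Polycomb components were at the 75.8 percentile, with Phf1 at 1.06 and Bmi1 at 0.91, and the heterochromatin genes at the 6.15 percentile. Interferon and antigen presentation genes were at the 78.1 percentile, with Cxcl10 at 0.93 and Oas1a at 0.69. The amino acid response list was at the 84.4 percentile, hypoxia and glycolysis at the 87.4, cholesterol synthesis at the 70.0 and immediate early genes at the 58.9, of which Ier2, on chromosome 8, had -0.87. Percentiles were 51.4 for heat shock and unfolded protein genes and 42.5 for proliferation genes. Xbp1, a transcription factor of the unfolded protein response, had 1.10 (0.88 ± 0.39, SD over 4 probe sets), and Ccne1, cyclin E1, had 1.12 on one probe set and 0.17 on another. Sex-chromosome markers were at the 15.8 percentile. The Y-linked genes Eif2s3y (550.7 and 870.9) and Uty (140.4 and 207.9) were above the floor on both arrays. So was Xist, on the X chromosome (406.7 and 479.6). These values are from the brightest probe set of each gene. Of all their probe sets, 1 of 3 for Xist, 1 of 2 for Eif2s3y and 2 of 4 for Uty were above the floor on both arrays. The Y-linked Kdm5d, chosen after its values were seen, was below the floor on both (35.9 and 40.3).

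**Figure D3:**
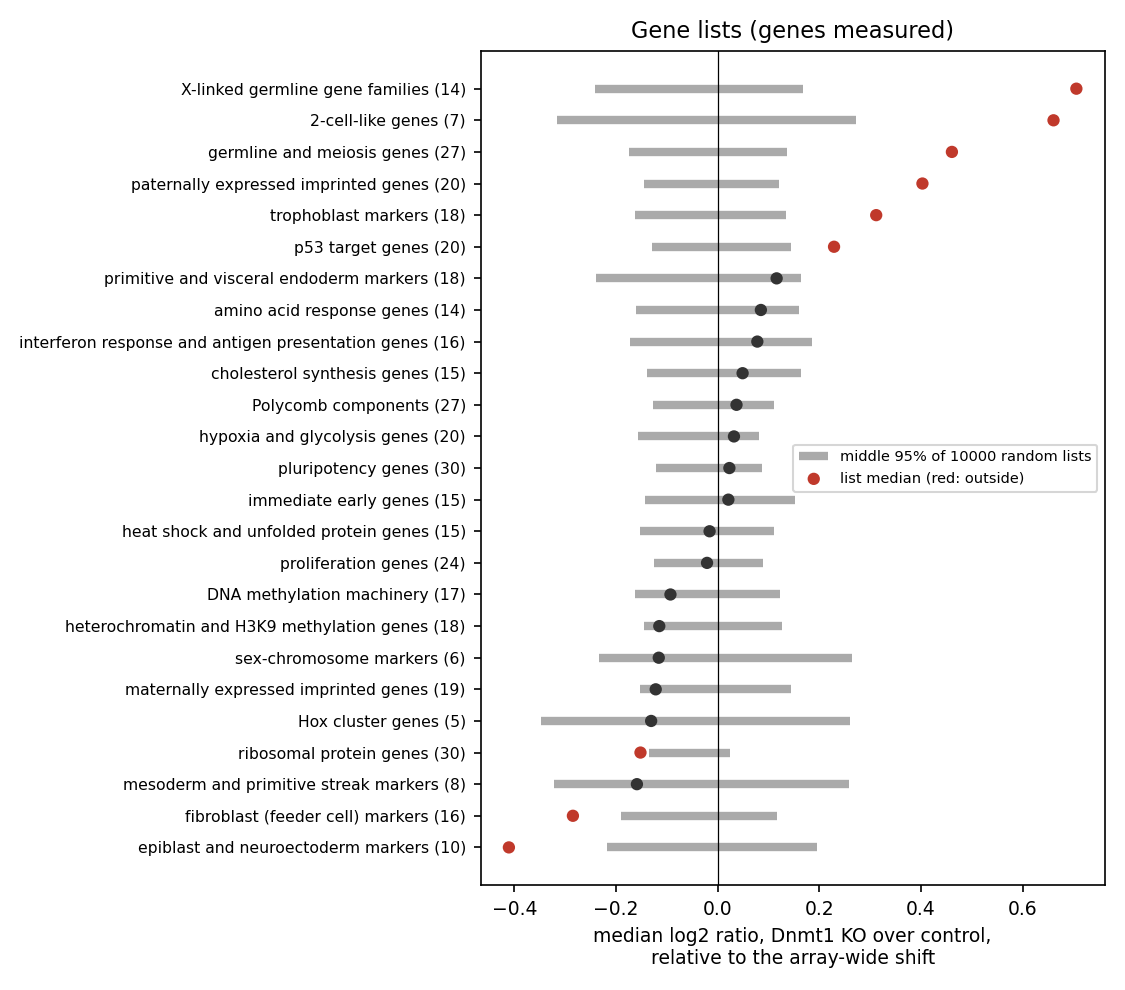
Median log2 ratio of each of the 25 gene lists, KO over control and relative to the array-wide shift (x axis), with the number of measured genes in brackets and the middle 95% of 10000 random lists matched on expression as grey bars. Points outside the bars are red, from 0.71 for the X-linked germline families to -0.41 for the epiblast and neuroectoderm markers, whose median was 0.01 as deposited.

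Ratios were also compared by chromosome. Chromosome 8 stood apart from the other chromosomes. Its 601 genes above the floor on both arrays had a median log2 ratio of -0.37 relative to the shift, or 0.06 as deposited, and 90.3% of them lay below the shift. The lowest of 10000 matched random lists had a median of -0.05. The other autosomes had medians between -0.04 (chromosome 3) and 0.07 (chromosome 11), and the X chromosome had -0.08. Chromosomes 5, 7, 11 and 17 above the shift and 3 and X below it also lay outside the middle 95% of random lists, with medians small beside that of chromosome 8. As deposited, every chromosome's median was above 0. Of the 65 genes at least 2-fold lower, 13 (20%) were on chromosome 8, which held 5.4% of the measured genes, and 1 of the 133 higher genes was.

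**Figure D4:**
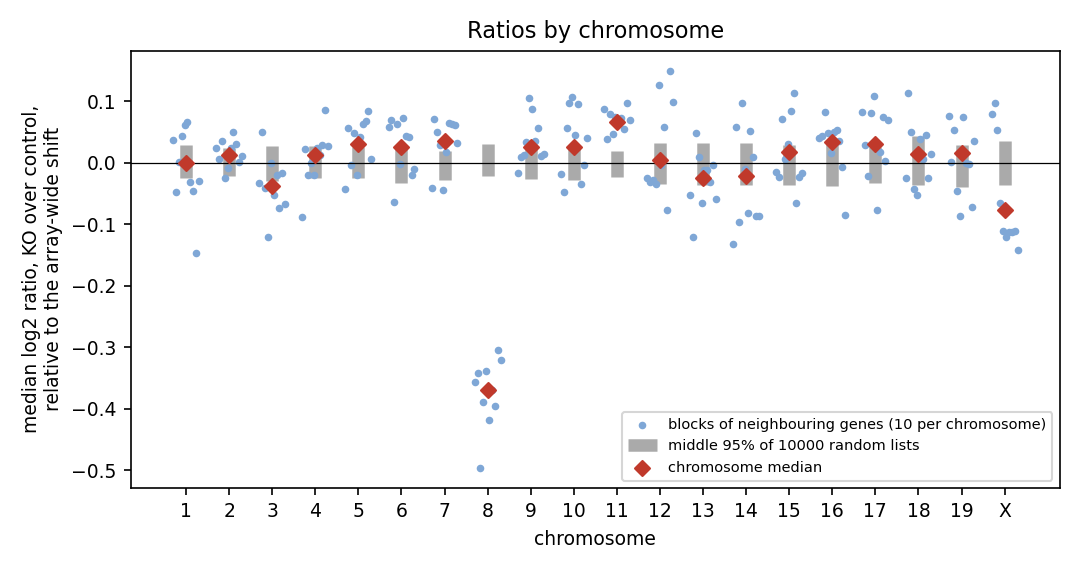
Median log2 ratio of the genes of each chromosome, KO over control and relative to the array-wide shift (red diamonds, y axis), with the medians of 10 blocks of neighbouring genes per chromosome in gene order (blue points) and the middle 95% of matched random lists (grey bars). All 10 blocks of chromosome 8 lie below 0 relative to the shift, and its median as deposited was 0.06.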

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

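Counts of genes depended on the scaling, the floor and the fold threshold. Against 602 higher and 12 lower as deposited, quantile normalization gave 153 and 53, centring 133 and 65, and lowess 159 and 48. Of the centred calls, quantile normalization kept 130 of 133 higher and 52 of 65 lower genes, and lowess 130 and 47. A floor at the 25th percentile gave 1174 and 117, at the 75th 233 and 4, and no floor 1920 and 678. As deposited, a threshold of 1.5-fold gave 3424 and 58, and of 3-fold 92 and 3. In settings added after the data were seen, the centred thresholds gave 579 and 519 at 1.5-fold and 32 and 6 at 3-fold, and leaving out chromosome 8 gave 132 and 52. The Dnmt1 log2 ratio stayed between -3.34 and -2.84 in every setting. With the floor at the 75th percentile, Ccdc138 and Misp3 had log2 ratios of 0.044 and 0.092 as deposited, since the KO signal was then at the floor. The lists of germline, X-linked germline, paternally expressed, 2-cell-like, trophoblast and p53 target genes stayed above the middle 95% of random lists in every setting, except that too few 2-cell-like genes were left to rank with the 75th percentile floor. Leaving out _x_at and _s_at probe sets touched no 2-cell-like or X-linked germline gene and 2 of 27 germline genes, so it tests little there. Ribosomal protein genes moved inside the middle range at 66.78 with quantile normalization, 30.61 with lowess, 2.6 with the 75th percentile floor and 4.32 without _x_at and _s_at probe sets. Fibroblast markers moved to 12.9 with the 75th percentile floor, where 8 genes were left, and epiblast and neuroectoderm markers to 7.26 without a floor. Maternally expressed genes moved below the middle range at 1.7 with quantile normalization, 2.4 with lowess, 0.0 with the 25th percentile floor and 0.03 without a floor. DNA methylation genes moved to 0.78 with the mean over probe sets, interferon genes to 97.95 with the 75th percentile floor, and immediate early genes to 99.77 without chromosome 8, which holds 2 of their 15 measured members. Chromosome 5 moved to the 96.35 percentile with lowess and 95.15 with the 75th percentile floor, and chromosomes 17 and 9 to 96.85 and 99.22 with lowess. Except where stated, the cause was not tested. No paired analysis was possible because each group has 1 array, and no replicate could be left out. Signals near the floor limit what can be said of genes that were dim on both arrays.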

Other observations

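The tests of copy number and its direction, of differentiated cells and of the X chromosome level were chosen or reworded after the result was seen, and the patterns of chromosome 8, the X chromosome and the zinc finger genes were themselves noticed in these data. Genes of the X chromosome were frequent among the genes higher on the KO array. Of 133 genes at least 2-fold higher relative to the shift, 19 (14.3%) were X-linked, against 3.4% of the measured genes, and 10000 random lists matched on expression held a median of 5 and at most 15. Of the 65 genes at least 2-fold lower, 5 (7.7%) were X-linked, a share not set against random lists. Of the 19 higher genes, 13 were outside the germline lists fixed in advance, among them Scml2 (log2 ratio at least 2.13), Tex13b (at least 1.73) and Tsx (at least 1.44), named here after their values were seen. Those lists were not complete, so being outside them does not mean that a gene is not a germline gene. A higher level of the whole chromosome was not what the array showed, since the median relative to the shift was -0.067 over the 414 measured X-linked genes and -0.076 over the 364 above the floor on both arrays. Blocks of neighbouring X-linked genes differed by position. Blocks 1 to 3 lay above the shift (0.053 to 0.098) and blocks 4 to 10 below it (-0.142 to -0.065).

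Several zinc finger genes stood near the top of the ratios (Zfp991 at 1.44, Zfp934 at 1.40, Zfp229 at 1.38, named after their values were seen). As a hypothesis, genes named Zfp were tested as a class. The 263 measured ones had a median of -0.04, at the 15.46 percentile of matched random lists, so the class was not higher. Of these 263, 3 were at least 2-fold higher and 2 at least 2-fold lower, beside 133 and 65 of all 12226 measured genes. The class was taken by name, so zinc finger genes under other names were not covered. Of the probe sets without an annotated gene, 2454 were above a floor, and 21 of these were at least 2-fold higher and 29 at least 2-fold lower.

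Genes of chromosome 8 were lower on the KO array along the whole chromosome. An intensity-dependent bias between the arrays is argued against by the lowess correction, after which the median was -0.389, with the lowest matched random list at -0.05. A few genes or one segment is argued against by the blocks of neighbouring genes, of which 10 of 10 lay below the array-wide median. The blocks of chromosome 11 all lay above that median, from 0.039 to 0.098, so blocks on a single side were not particular to chromosome 8. A difference in copy number of the whole chromosome between the cultures is a candidate explanation: its range was set with the median of -0.369 already seen, so the blocks alone could have come out against it. An extra copy in the control culture and a missing copy in the KO culture cannot be told apart, since the fold of 0.774 lies above both 0.667 and 0.5, the values for these without compression of array ratios. Whether a changed copy number has any link to Dnmt1 is open.

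Germline genes were higher on the KO array. A trend with signal level shared by all genes is argued against, since the random lists were matched on mean expression. The lowess correction, after which the list stayed at the 100 percentile, adds little to that matching. It was fitted only on probe sets above the floor on both arrays, so a bias of the dim probe sets themselves stays open. Cross-hybridization with related transcripts cannot be told apart, since leaving out _x_at and _s_at probe sets (100 percentile) touched 2 of the 27 measured members. The loss of Dnmt1, which the design names, may account for the pattern. A different source line or passage of the control culture cannot be told apart from it with 1 array per group and no label for either.

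Klf4, Nr0b1, Nanog, Lefty2, named after its value was seen, and Esrrb were at least 2-fold higher on the KO array, Esrrb only on its brightest probe set, since its 3 probe sets averaged 0.84. Whether fewer differentiated cells in the KO culture were the whole cause could not be decided. The median of the 30 measured pluripotency genes was 0.023 (SD between genes 0.62), so the list as a whole was not higher. The smallest of these 5 genes had 1.10, but they were picked for being at least 2-fold higher, so a gap was built in. That fewer differentiated cells would raise all pluripotency genes by about the same amount was assumed and not tested. The lists of differentiated cells went different ways. The percentiles were 0.01 for epiblast and neuroectoderm (7.26 without a floor) and 0.13 for fibroblasts (12.9 with the 75th percentile floor). They were 21.92 for mesoderm, 89.14 for endoderm and 100 for trophoblast. Below the floor on both arrays, and so not ranked, were 15 of 25 epiblast and neuroectoderm and 9 of 25 fibroblast genes on the array. For mesoderm, endoderm and trophoblast these were 12 of 20, 8 of 26 and 5 of 23. A contribution of fewer epiblast, neural or fibroblast cells could not be decided from the ranked members and stays open. An effect of Dnmt1 loss on these genes is open and untested.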
